A study of Mus musculus with 9 samples.

How the data were processed

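Gene expression was measured in periprostatic fat, the adipose depot around the prostate, of 9 male C57BL/6J mice on Affymetrix Mouse Gene 2.0 ST arrays. Per the labels' protocols, 5 mice ate a diet with 60 percent of its energy as fat and 4 mice a diet with 10 percent, from 6 weeks of age for 12 weeks, and tissue was taken at 18 weeks. The RNA was extracted from frozen tissue, and per the labels' protocols only samples with an RNA integrity number above 7 were hybridised. Each array carries 1 mouse, as the sample titles state, and no sample was pooled.

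The deposited values are log2 expression values per probe set. Per the submitters' processing notes the tools were RMA, a method that corrects background, normalizes quantiles across arrays and summarises probes, limma and R 3.5.0, with no role or order given. The software that ran RMA, the annotation version and any filter on rows are not given in the sources used here. The values lie between 4.41 and 14.2, and arrays differed slightly in median and spread. Arrays of high fat mice 1 and 2 had a median of 6.45 and an SD of 1.87, whereas the medians of the other 7 arrays lay between 6.48 and 6.50 and their SDs between 1.83 and 1.85 (log2 units over all rows of the table). RMA equalises the distributions of probes before they are summarised, so small differences can remain. Whether the 9 arrays were normalized together or in more than 1 batch is not given in the sources used here. No detection calls were used, so whether a dim gene lay above background could not be determined. Whether bright probes approach saturation was not determined either, so folds of genes with a group mean far above or below most others hold for the values as deposited. Precision is limited by the number of arrays. Scan dates and hybridisation batches are not given in the sources used here.

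The table has 33793 rows. The probe table lists 25335 of them: 23521 with 1 gene symbol, 1814 with several and 8458 rows are not listed. Symbols were checked through Entrez gene identifiers against a reference table of the mouse assembly GRCm38.p6, which matched 23328 probes and changed 0 symbols. That table served for names only. Where several probes shared 1 symbol (1082 genes), the probe with the highest mean over the 9 arrays was kept, which left 22180 genes. Probes with several symbols, or none, entered no gene result.

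Diet was tested with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3 on the deposited log2 values, with an intercept and diet and no covariate. Benjamini-Hochberg adjustment ran over all 22180 genes and the threshold was an adjusted p of 0.05, with no fold threshold. Differences are high fat minus low fat on the log2 scale with the moderated standard error (SE), and folds are powers of 2 of these differences. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 33 lists with at least 3 measured members. Beside camera stand its p with an estimated correlation, the rotation test fry, and a two-sided exact permutation test of each list's mean value per mouse over all 126 assignments of the mice to groups of 5 and 4, whose smallest possible p is 0.0159. Of 562 entries on the lists, some of them genes on more than 1 list, 511 were measured, 3 of them listed under an older name.

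The design, the lists and the naming rule were fixed before the data were examined. The lists cover adipocytes and their metabolism, immune and stromal cells, stress and proliferation, the clock, and other tissue that a dissection near the prostate can carry. Part 1 of the rule names the 12 genes higher and the 12 genes lower with the largest difference among genes past the threshold whose groups of arrays do not overlap, leaving out predicted or unnamed gene models and gene classes such as olfactory receptors. Part 2 names, in each list that camera called, the 4 members with the smallest p in the list's direction, and in each other list the 2 with the smallest p. Part 3 names Lep, Adipoq, Pparg, Fasn, Scd1, Ccl2, Tnf, Itgax, Adgre1, Cyp19a1 and Ucp1 whatever their values. Members named beyond this rule, in counts of 5 or fewer, were chosen after their values were seen.

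The procedure was tested on simulated data for the diet comparison of 22180 genes with 50 changed genes at each size. It recovered 22 of 50 at a log2 difference of 0.25, 38 of 50 at 0.5, 47 of 50 at 1 and 50 of 50 at 2, with 7 false calls among 164. The simulation changed far fewer genes than changed in the data and drew noise independently for each gene. Its rates therefore need not hold for the real comparison. Alternatives covered normalization, centring of arrays, a filter on dim genes, the choice among probes, the variance model, array weights, the mouse number as a block, a score of prostate and seminal vesicle genes as a covariate, all rows of the table, a fold threshold, a looser adjusted p, other list tests, and leaving out each mouse. After the data had been examined, fits without high fat mice 1 and 2, and without high fat mouse 1 and low fat mouse 2, were added.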

Results

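Transcript levels were compared in periprostatic fat of mice fed a high fat diet (5 mice) or a low fat diet (4 mice), in a study of diet-induced obesity. The comparison asks which genes differ in this depot between the diets after 12 weeks. Values are log2 expression from 1 array per mouse, over 22180 genes, and the number of arrays limits the precision.

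The diets separated on the first principal component, which held 62.0% of the variance, with all 5 high fat mice on one side and all 4 low fat mice on the other. Low fat mouse 2 lay apart on the second component, which held 9.18%. Correlations between arrays across genes ran from 0.973 to 0.989 between diets and from 0.991 to 0.996 within them. Skeletal muscle genes were high in high fat mouse 1, with a mean log2 value of 8.31 over the list against 6.31 to 6.41 in the other high fat mice. Smooth muscle genes were high in low fat mouse 2, at 9.51 against 7.95 to 8.04 in the other low fat mice.

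Of the 12 largest increases in high fat diet, Atp6v0d2, Gpnmb, Trem2, Mmp12 and Itgax were on the list of lipid-associated macrophage genes. Atp6v0d2, a subunit of the vacuolar proton pump (probe set 17423577), was 31.7-fold higher, with a log2 difference of 4.98 ± 0.26 (SE). Tm4sf19, a membrane protein of the transmembrane 4 L6 family, was 15.9-fold higher, the integrin gene Itgad 14.9-fold, and Gpnmb, a lysosomal glycoprotein, 12.1-fold. Trem2, a lipid-sensing receptor of macrophages, rose 10.4-fold, Mmp12, the macrophage elastase, 10.1-fold, and Itgax, which encodes CD11c, 8.78-fold. Il7r, which encodes the interleukin-7 receptor alpha chain, rose 9.42-fold.

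The other genes named by size of increase were Gpr50, a receptor related to the melatonin receptors (12.0-fold), Rnf128, a ubiquitin ligase (7.94-fold), Slc5a7, a choline transporter (7.80-fold), and Adam8, a membrane metalloproteinase (7.55-fold). The largest decrease was that of Pon1, the paraoxonase of high density lipoprotein (probe set 17464614), which was 8.40-fold lower. Cyp2f2, a cytochrome P450, was 5.97-fold lower, Fam13a 5.09-fold, Eci3, an enoyl-CoA isomerase, 4.34-fold, the claudin gene Cldn22 4.31-fold and Alb, which encodes albumin, 4.02-fold. The immunoglobulin genes Iglv1 (7.48-fold), Igkv9-120 (4.73-fold) and Jchain (3.91-fold) were lower, as were Orm3 (5.96-fold), Serpina3b (4.84-fold) and Ces1f (3.70-fold). Iglv1, Igkv9-120, Orm3, Serpina3b and Ces1f belong to families of similar genes whose probes can share signal, so which family member changed is uncertain. Low fat means of Tm4sf19 (6.66), Atp6v0d2 (6.53), Gpr50 (6.48), Itgad (6.29) and Rnf128 (5.80) lay near or below the medians of the arrays. So did high fat means of Orm3 (6.66), Serpina3b (6.62), Cldn22 (6.32), Eci3 (6.21) and Pon1 (6.00). Whether these means lie above background was not determined, so these folds hold only for the values as deposited. All 24 of these genes passed the limma test by the rule that named them, with adjusted p from 3.49e-06 for Itgad to 0.0131 for Jchain. Gene Iglv1 no longer passed without high fat mice 1 and 2 (log2 difference -2.77). Without low fat mouse 2 the order of decreases turned, with gene Iglv1 at -3.24 and gene Pon1 at -2.52, and gene Serpina3b was at -1.67 against -2.28 in all mice.

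By limma with Benjamini-Hochberg adjustment, 4768 genes changed by diet (21.5%), with 2742 genes higher in high fat diet and 2026 genes lower in high fat diet. At a log2 difference of at least 1, 283 were higher and 94 lower. The arrays of the diets did not overlap in 4602 genes (20.7%), against 1.59% by chance. The split between directions moved with scaling, to 2320 higher and 2771 lower with quantile normalization repeated on these genes and to 2227 and 3056 with arrays centred on their medians. High fat mice 1 and 2, whose arrays had wider distributions of a source that was not determined, were left out together in a fit chosen after the data were seen, and 3210 genes then changed, 1716 of them higher and 1494 lower.

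**Figure D1:**
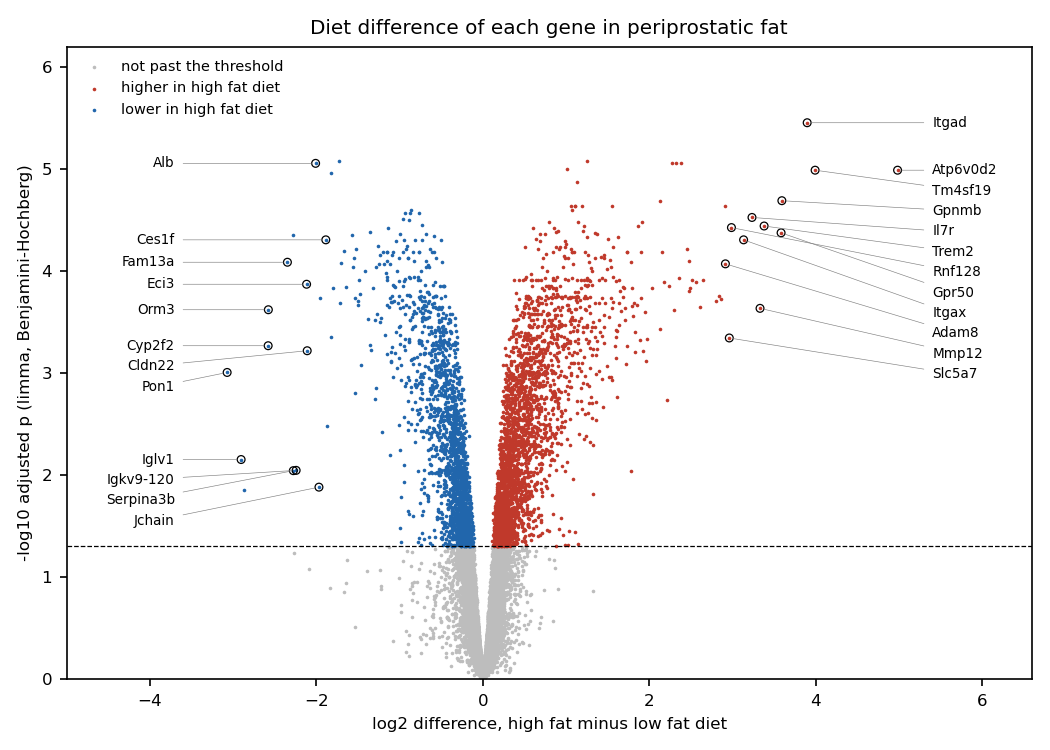
Log2 difference (high fat minus low fat diet, x axis) against -log10 of the limma adjusted p (y axis) for each of 22180 genes, with a dashed line at the threshold of 0.05. Red and blue points are the 2742 genes higher and 2026 genes lower in high fat diet, grey points did not pass, and circled names are the 24 genes named by size, from Pon1 at -3.07 to Atp6v0d2 at 4.98.

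Among genes fixed for their role in adipose tissue, Lep, the leptin gene, was 1.51-fold higher in high fat diet, at 13.2 ± 0.13 (SD, n = 5) against 12.6 ± 0.24 (SD, n = 4) on the log2 scale. Adipoq, the adiponectin gene, was 1.28-fold lower, at 11.2 ± 0.13 (SD, n = 5) against 11.5 ± 0.03 (SD, n = 4). Pparg, the master regulator of adipocyte differentiation, was 1.27-fold lower, and Fasn, the fatty acid synthase gene, 1.62-fold lower. The chemokine gene Ccl2 was 6.11-fold higher, the macrophage gene Adgre1 2.25-fold and the cytokine gene Tnf 1.78-fold. Limma adjusted p was 0.00356 for Lep, 0.00359 for Adipoq, 0.00564 for Pparg, 0.000239 for Fasn, 0.000597 for Adgre1 and 0.000184 for Tnf. Scd1, a fatty acid desaturase gene, fell by 0.15 ± 0.04 (SE) with a limma adjusted p of 0.0279. With quantile normalization repeated the difference of gene Scd1 was -0.02, which did not pass. Ucp1, the uncoupling protein of brown fat, was at 5.92 ± 0.03 (SD, n = 5) in high fat mice and 6.21 ± 1.01 (SD, n = 4) in low fat mice, a difference that did not pass the limma test (adjusted p = 0.638). Low fat mouse 2 alone was at 7.72, and without it the difference of gene Ucp1 was 0.21, turned in direction and past the threshold. All other mice lay at 5.66 to 5.97, below the medians of the arrays. Whether these Ucp1 values lie above background was not determined. Cyp19a1, the aromatase gene, was not analysed here.

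**Figure D2:**
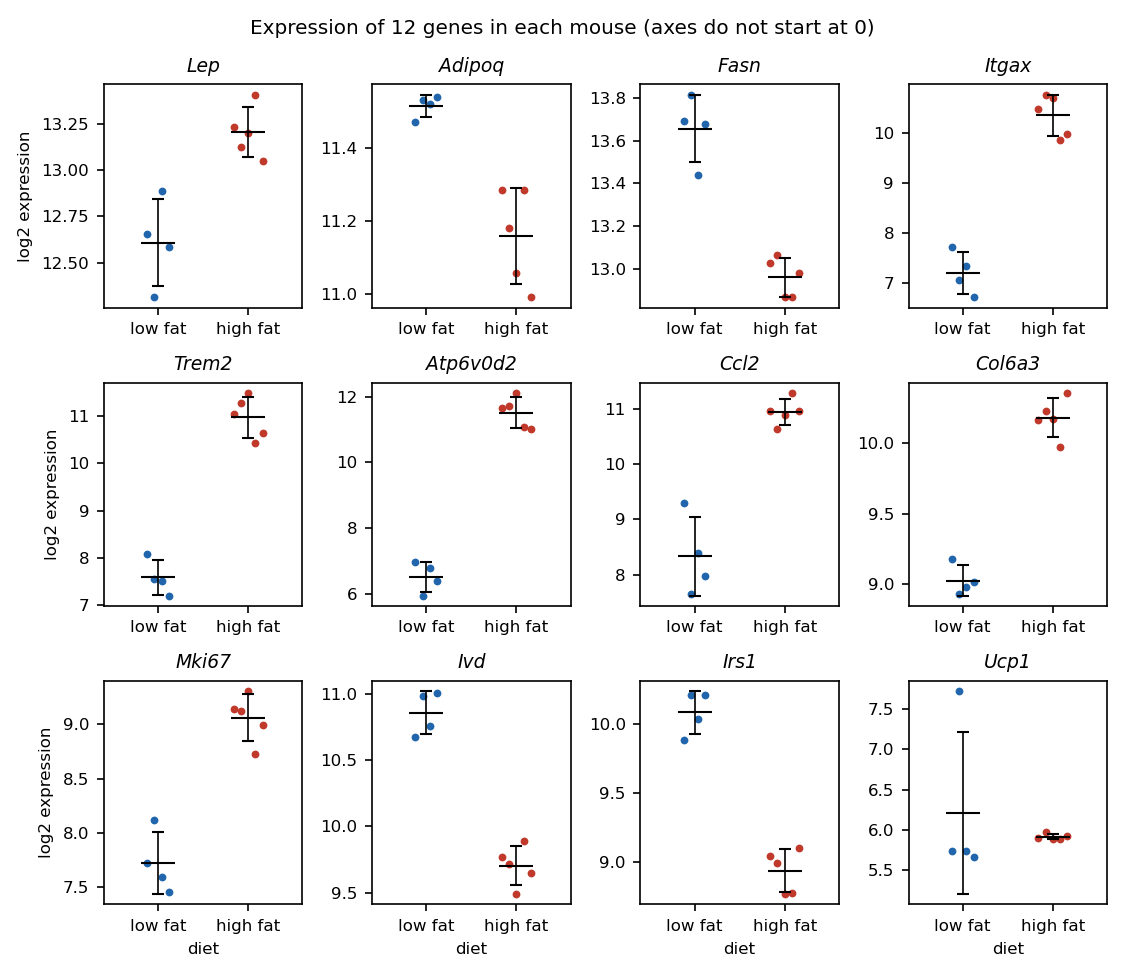
Log2 expression (y axes, each with its own range and not starting at 0) of 12 genes in each mouse, by diet (x axes). Points are mice, horizontal lines are means and bars are SDs over 4 low fat and 5 high fat mice; Atp6v0d2 lies at 11.5 in high fat and 6.53 in low fat mice on average, and the high Ucp1 point is low fat mouse 2 at 7.72.

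Macrophage genes rose together in high fat diet. In the lipid-associated macrophage list, 15 of 17 measured members rose and 1 fell (16 and 1 adjusted over the list alone), led by Atp6v0d2, Gpnmb, Trem2 and Lipa, the lysosomal acid lipase gene, which was 2.84-fold higher. The member that fell was Acp5 (-0.51). In the general macrophage list, 15 of 19 members rose and 1 fell (16 and 1 adjusted over the list alone). Its leading members were Cd68 (3.66-fold), the complement gene C1qb (1.89-fold), Mpeg1 (2.74-fold) and Ms4a7 (3.72-fold), and Timd4, a receptor of resident macrophages, fell (-0.44). Cytokine and chemokine genes rose in 8 of 23 members (9 rose and 1 fell adjusted over the list alone), among them Ccl7 (6.28-fold), Ccl2 (6.11-fold), Il1rn, the interleukin-1 receptor antagonist gene (3.09-fold), and Tnf (1.78-fold). Antigen presentation genes of class II rose in 4 of 12 members (6 adjusted over the list alone), by smaller amounts: H2-DMb1 1.64-fold, H2-Aa 1.29-fold, H2-Ab1 1.25-fold and H2-Eb1 1.16-fold. With arrays centred on their medians gene H2-Eb1 no longer passed (0.17), and without high fat mice 1 and 2 gene H2-Ab1 no longer passed (0.31). Camera adjusted p was 1.72e-14 for lipid-associated macrophage genes, 3.01e-08 for macrophage genes, 0.000384 for cytokines and chemokines and 0.00494 for class II genes. With an estimated correlation none of these lists passed (camera adjusted p = 0.196, 0.196, 0.137 and 0.341 in that order), and the exact permutation test did not call list antigen presentation class II (adjusted p = 0.0582, range over alternatives 0.00124 to 0.341).

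Among the lymphoid and granulocyte lists, camera at the preset correlation called only the B and plasma cell list. Whether these lists differed from each other was not tested. The B and plasma cell list was called lower by camera (adjusted p = 0.0016, and adjusted p = 0.578 with an estimated correlation), with 2 of 14 members down (4 adjusted over the list alone), Jchain 3.91-fold and Mzb1 1.37-fold. Ms4a1 (-1.13) and Bank1 (-0.86) had limma adjusted p of 0.0503 and 0.0563, and fry and the exact permutation test of list B and plasma cell did not pass (adjusted p = 0.114 and 0.138, range over alternatives 1e-05 to 0.578). In the T and NK cell list, 1 of 18 members rose, Il7r, and 1 fell, Ncr1, by 0.49 (the same counts adjusted over the list alone). Its median was -0.07 and its mean 0.04, and camera, which pointed down, did not call it (adjusted p = 0.355). In the neutrophil and mast cell list, 1 of 14 members rose, S100a8 (log2 difference 1.03), and 2 fell, Mmp9, 3.26-fold lower, and Retnlg (-0.21), with the same counts adjusted over the list alone and a camera adjusted p of 0.858. In the interferon response list, 0 of 16 members passed limma over all genes or adjusted over the list alone, 1 at an unadjusted p under 0.05; Isg15 was at 0.19 and Mx1 at 0.24, and camera did not call the list (adjusted p = 0.7).

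Matrix and proliferation genes rose in high fat diet. In the extracellular matrix list, 22 of 24 members rose (23 adjusted over the list alone), with the collagen genes Col6a3 at 2.22-fold, Col6a1 at 2.09-fold and Col4a2 at 1.69-fold, and the cross-linking enzyme gene Lox at 1.98-fold. In the proliferation list, all 18 members rose (18 adjusted over the list alone), among them Mki67 (2.54-fold), Kif11 (2.20-fold), Ube2c (1.98-fold) and Aurka (1.58-fold). Immediate early and heat shock genes rose in 7 of 17 members (7 adjusted over the list alone), led by Atf3 (5.47-fold), Fos (2.92-fold) and Egr2 (2.64-fold). Hspb1 was 1.29-fold higher, and gene Hspb1 no longer passed with the mean of its probes (0.15). In the unfolded protein response list, 8 of 17 members rose and 2 fell (10 and 2 adjusted over the list alone). Atf3 is also in that list, followed by Sdf2l1 (2.06-fold), the chaperone gene Hspa5 (1.38-fold) and Sel1l (1.20-fold), while Asns (-0.84) and Xbp1 (-0.33) fell. Adipocyte progenitor and fibroblast genes rose in 5 of 17 members and 1 fell, Pparg (6 and 2 adjusted over the list alone). Icam1 was 1.53-fold higher, Pdgfra 1.62-fold, Pdgfrb 1.34-fold, Clec11a 1.44-fold, and Cd34 was the other one (0.37). Camera adjusted p was 7.38e-19 for matrix, 1.72e-14 for proliferation, 0.000105 for immediate early, 0.00184 for unfolded protein response and 0.0439 for progenitor genes. With an estimated correlation none of these lists passed (camera adjusted p = 0.137, 0.196, 0.196, 0.196 and 0.545 in that order), and list adipocyte progenitor and fibroblast did not pass with dim genes left out (camera adjusted p = 0.148), with quantile normalization repeated (0.0611) or by the exact permutation test (0.0582), with a range over alternatives of 0.00778 to 0.545.

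Lists of branched chain amino acid breakdown, fatty acid synthesis, adipocyte identity and insulin signalling were called lower in high fat diet by camera at the preset correlation. All 18 measured genes of branched chain amino acid breakdown fell (18 adjusted over the list alone), among them Ivd, isovaleryl-CoA dehydrogenase (2.22-fold lower), Aldh6a1 (2.09-fold), Mccc2 (1.70-fold) and Pccb (1.66-fold). Fatty acid synthesis genes fell in 15 of 17 members (16 adjusted over the list alone). Acaca and Acacb, which encode the acetyl-CoA carboxylases, were 3.14-fold and 2.83-fold lower, Thrsp 2.66-fold and Fasn 1.62-fold. In the adipocyte identity list, 13 of 16 members fell (14 adjusted over the list alone), with Pck1 3.53-fold, the glucose transporter gene Slc2a4 2.30-fold, Acvr1c 1.86-fold and the transcription factor gene Cebpa 1.51-fold lower. Insulin signalling genes fell in 9 of 17 members and rose in 2 (11 and 2 adjusted over the list alone). Irs1 was 2.21-fold lower, Pde3b 2.01-fold and Insr, the insulin receptor gene, 1.39-fold, while Ptpn1 (0.35) and Akt1 (0.35) rose. Camera adjusted p was 2.02e-15 for branched chain amino acid breakdown, 4.58e-11 for fatty acid synthesis and for adipocyte identity, and 0.000116 for insulin signalling. With an estimated correlation none of these lists passed (camera adjusted p = 0.196 for each).

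In the lipolysis and lipid droplet list, 8 of 13 members fell and 2 rose (8 and 3 adjusted over the list alone), with Plin1 1.39-fold, the triglyceride lipase gene Pnpla2 1.32-fold and Lipe 1.27-fold lower. Pde3b is in that list too, and the members that rose were Hilpda (1.15) and Plin2 (0.77). Oxidative phosphorylation genes fell in 10 of 24 members (13 adjusted over the list alone), by small amounts such as 1.41-fold for Sdha, 1.32-fold for Uqcrc2, 1.31-fold for Ndufb8 and 1.27-fold for Cyc1. In the circadian clock list, 8 of 15 members fell and 1 rose (9 and 2 adjusted over the list alone). Per3 was 2.21-fold lower, Dbp 1.97-fold, Nr1d1 1.77-fold and Tef 1.57-fold, and Nfil3 rose (0.56). Camera adjusted p was 0.00749 for lipolysis, 1.86e-06 for oxidative phosphorylation and 0.0089 for clock genes, and 0.33, 0.341 and 0.293 with an estimated correlation. The exact permutation test did not call list oxidative phosphorylation (adjusted p = 0.0582, range over alternatives 3.25e-09 to 0.341).

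Several metabolic lists held members that moved in both directions and were not called by camera. In the adipose expansion list, 3 of 6 members rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.102): Lep, Bmp3 (0.82) and Mest (1.78) rose, and Nnat was 1.87-fold lower. The adipose expansion list's mean log2 value was 10.3 in low fat mouse 2, against 11.3 to 11.7 in the other low fat mice. In fatty acid oxidation, 6 of 15 members fell and 1 rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.121), with Hadh 1.26-fold lower and Cpt1a, the carnitine palmitoyltransferase of mitochondrial entry, 1.56-fold higher. Cholesterol synthesis genes rose in 2 of 15 members, Dhcr7 (1.46-fold) and Hmgcs1 (0.38), and fell in 1, Fdft1 (1.75-fold lower), with the same counts adjusted over the list alone and a camera adjusted p of 0.0883. In the thermogenic adipocyte list, 3 of 15 members rose, Otop1 (3.79-fold), Tmem26 (0.27) and Kng2 (0.39), and 3 fell, Ppargc1a (1.66-fold lower), Ucp3 (-0.45) and Cidea (-0.99), with the same counts adjusted over the list alone (camera adjusted p = 0.905). In the hypoxia and angiogenesis list, 4 of 14 members rose, Hif1a (1.31-fold), Angptl4 (0.39), Pgk1 (0.32) and Car9 (0.23), and 5 fell, Pdk1 (1.27-fold lower), Vegfa (-0.52), Epas1 (-0.30), Bnip3 (-0.35) and Ndrg1 (-0.32). Adjusted over the list alone 5 rose and 5 fell, the median was 0.13 and the mean -0.0004, and camera did not call it (adjusted p = 0.836). In the sex steroid list, 2 of 12 members fell, Hsd11b1 (1.53-fold lower) and the estrogen receptor gene Esr1 (1.34-fold lower), and 2 rose, Srd5a3 (0.34) and Hsd17b7 (0.39), with the same counts adjusted over the list alone. Camera did not call the sex steroid list (adjusted p = 0.44), whereas fry and the exact permutation test called list sex steroid (adjusted p = 0.0151 and 0.0374, range over alternatives 0.0151 to 0.604).

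Endothelial, mesothelial and muscle lists were not called by camera. In the endothelial list, 1 of 16 members rose, Vwf (1.31-fold), and 2 fell, Kdr (1.20-fold lower) and Robo4 (-0.25), with 1 up and 0 down adjusted over the list alone and a camera adjusted p of 0.0633. With quantile normalization repeated camera called list endothelial cell lower (adjusted p = 0.0314, range over alternatives 0.0153 to 0.609). In the mesothelial list, 0 of 13 members passed limma over all genes or the list alone, and 0 had an unadjusted p under 0.05; Msln was at 0.70, Gpm6a at 0.69, the list's median at 0.28, and the camera adjusted p was 0.172. With arrays centred on their medians camera called list mesothelial cell higher (adjusted p = 0.045, range over alternatives 0.0131 to 0.85). Smooth muscle genes rose in 1 of 11 members, Synpo2 (1.57-fold, also adjusted over the list alone), and Acta2 was at 0.35. The median of that list was -0.03, its mean -0.16 and camera pointed up without a call (adjusted p = 0.999), but without low fat mouse 2 the median of list smooth muscle was 0.21 and camera called it. In the skeletal muscle list, 0 of 12 members passed limma over all genes or the list alone and 0 had an unadjusted p under 0.05; Myh2 was at 0.35 and Mb at 0.18 (camera adjusted p = 0.579).

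In the prostate epithelium list, 1 of 15 members rose, Mme (0.24), and 2 fell, Azgp1 (1.31-fold lower) and Trp63 (1.12-fold lower), with the same counts adjusted over the list alone and a camera adjusted p of 0.606. Its mean log2 value was 6.08 ± 0.06 (SD, n = 5) in high fat and 6.11 ± 0.04 (SD, n = 4) in low fat mice. In the seminal vesicle and epididymis list, 0 of 17 members passed limma over all genes or the list alone, 2 had an unadjusted p under 0.05, Sva (-0.09) and Lcn8 (0.26), and the camera adjusted p was 0.905. That list's mean was 5.34 ± 0.03 (SD, n = 5) and 5.33 ± 0.01 (SD, n = 4). Of 4 blood cell genes, 1 rose, the platelet gene Pf4 (1.31-fold, also adjusted over the list alone), and Ppbp was at -0.20. The blood list's mean per mouse lay between 7.67 and 7.99, its median difference was -0.04 and its mean difference 0.03, and camera, which pointed down, did not call it (adjusted p = 0.999).

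Over all 33 lists, camera at the preset correlation called 17, of which 9 were up and 8 down. With an estimated correlation camera called 0, and 7 had an unadjusted p under 0.05, while fry called 17 and the exact permutation test 14. At the preset correlation, 22 of 100 groupings of the mice, the real one included, called as many lists. Other groupings among these still held the diets in unequal shares.

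**Figure D3:**
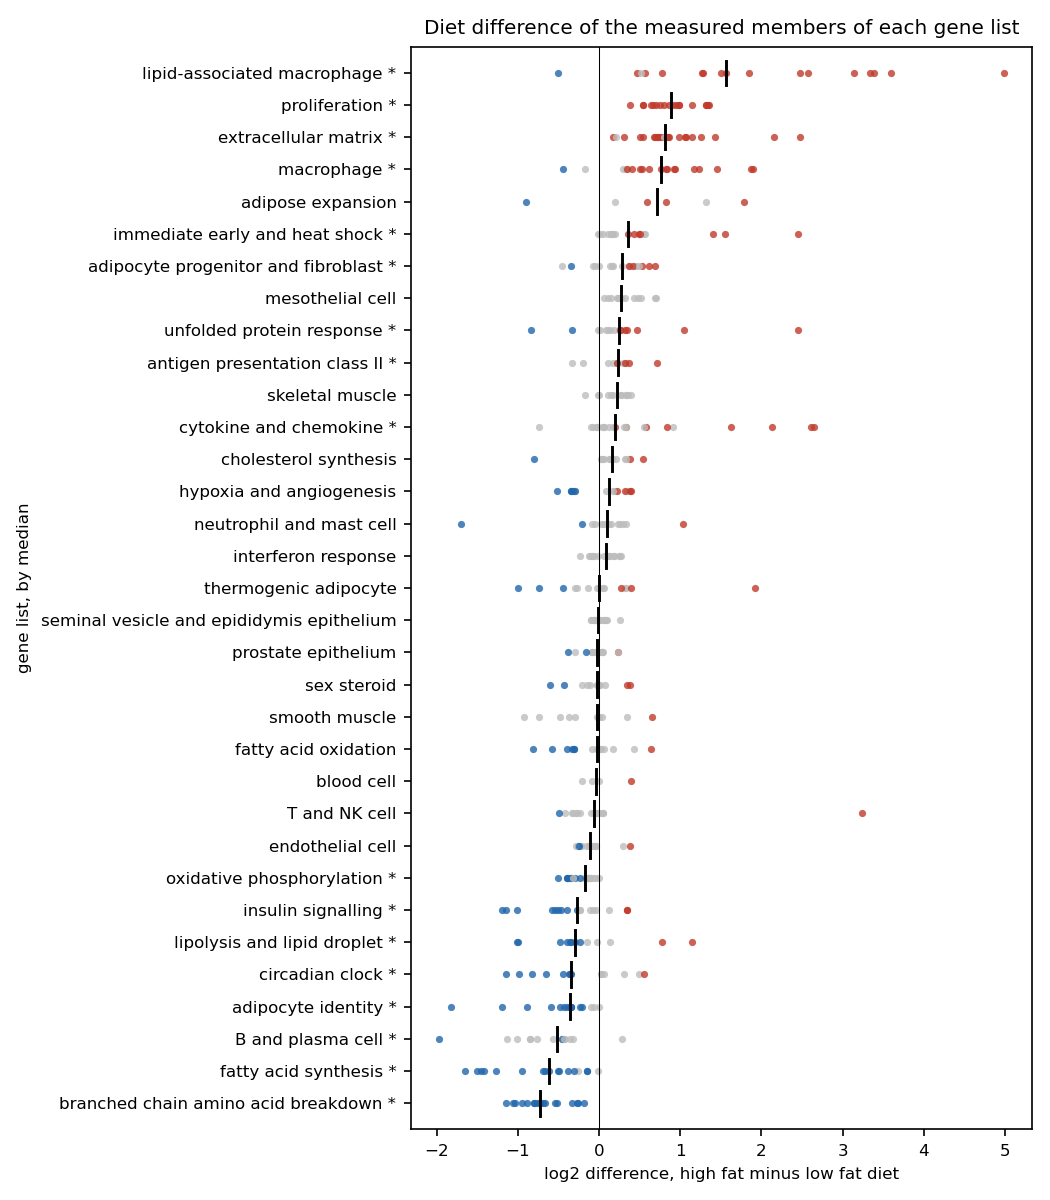
Log2 difference (high fat minus low fat diet, x axis) of each measured member of the 33 gene lists (y axis, ordered by median). Points are genes, red or blue where they passed the limma threshold upward or downward and grey otherwise, black bars are list medians, and an asterisk marks the 17 lists called by camera at the preset correlation; medians run from -0.73 for branched chain amino acid breakdown to 1.56 for lipid-associated macrophage genes.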

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

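In this part, the tests of the macrophage and endothelial scores and of the spread of adipocyte genes were chosen after the result was seen, as was their repeat without Pck1; predictions for the clock genes, muscle genes and other groupings were written after the main results had been seen and before these tests were run.

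Macrophage genes were higher and adipocyte genes lower in high fat mice, which a lower share of adipocyte RNA could produce. Such a share raises markers of every other cell type alike, yet the macrophage score rose over the endothelial score by 0.8424 log2 units (two-sided exact permutation p = 0.0159, the smallest these mice can give). Dilution would also lower genes made only by adipocytes by 1 amount. Of 6 adipocyte identity members with a mean below 12 over all 9 arrays, 5 had a 95 percent interval that left out their median of -0.74. The other 10 of 16 were left out, with 12 an assumed bound against saturation. Without Pck1, which lay above 12 in low fat mice, 4 of 5 did (median -0.60, the value of the member Cebpa). Whether other cells also express these genes was not determined, so the unequal falls cannot decide about dilution. The scores compared above had already been seen, so the permutation p is no independent test. The macrophage score rose by 0.75 while the endothelial score did not rise (-0.09). This argues against an equal rise of all other cell types as the whole cause. Dilution in part, more macrophages, a change within macrophages and an effect of diet on adipocyte genes stay open.

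Clock genes were lower, led by Per3, Dbp and Nr1d1, and a different time of day at sampling may produce this as well as diet. The genes grouped with Arntl (Arntl, Clock, Npas2, Nfil3 and Cry1, of which Nfil3 and Cry1 encode repressors) had a median difference of 0.3027, but only Nfil3 of 5 passed the threshold, so phase and diet cannot be told apart; what keeps it open is that sampling times were not used here. The score of these 5 genes rose over that of 10 other clock genes, Per3, Dbp and Nr1d1 among them, by 0.8311 (exact permutation p = 0.0159). Both sets come from the clock list, whose differences had already been seen, so this contrast cannot decide about dilution of clock transcripts.

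Muscle genes stood out in single mice. The skeletal muscle score of high fat mouse 1 was 8.311 against 6.31 to 6.41 in the other high fat mice, Myh2 was 7.004 there, and low fat mouse 4 had a skeletal score of 7.098. Of 12 further skeletal muscle genes 10 were highest in high fat mouse 1, as were 12 of 12 list genes, with Acta1 at 11.0 and Myh4 at 8.95, which fits muscle fibres in that sample as a candidate source. The smooth muscle score of low fat mouse 2 was 9.513, and 7 of 11 further smooth muscle genes and 9 of 11 list genes were highest there. Des was at 11.2 there, Myh11 at 10.3 and Actg2 at 9.97, with Actg2 at 5.88 to 6.30 in the other mice. Stray smooth muscle and a change in resident cells cannot be told apart. Without low fat mouse 2, list smooth muscle had a median of 0.20919. No biological explanation was tested for either mouse, since the labels give none.

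The remaining single-mouse values stood out by the ratio of their gap to the range of their group, some by a small gap, such as Gpr50 at 6.524 against 6.467 to 6.47. Low fat mouse 1 had an insulin signalling score of 10.05, that Gpr50 value, Hadh at 13.24 and Rnf128 at 5.928. Low fat mouse 2 had Cyc1 at 11.44, Lcn8 at 5.528 and Ucp1 at 7.723. Low fat mouse 4 had C1qb at 11.38 and Mmp9 at 10.06. High fat mouse 2 had Azgp1 at 6.049 and Icam1 at 8.921, and high fat mouse 3 a seminal vesicle and epididymis score of 5.4. High fat mouse 4 had a neutrophil and mast cell score of 7.159 and Sdf2l1 at 9.482. High fat mouse 5 had H2-Aa at 12.19 and S100a8 at 7.435. In all, 20 of 308 such checks stood out (6.49%), where chance alone gives about 1 in 20.

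Among 10272 table rows without a single gene name, 386 were higher and 473 lower in high fat diet by limma over all rows, and these were not part of the gene results.

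Other groupings of the same mice were fitted, 100 of the 126 possible. The real grouping gave 4768 genes, and 1 of 100, the real one itself, gave as many; the highest other gave 2009, and that grouping held only 1 high fat mouse among its 5, close to the mirror of the real one. The number of genes was thus larger than in any other grouping fitted, though not all possible groupings were fitted. Mixed groupings hold the diet difference within their groups, so their low counts are not those of mice alike in diet. A factor that ran together with diet would give the same result. For the 17 lists called at the preset correlation, 22 of 100 groupings gave as many. The highest other gave 21 and the median of the others was 12. The grouping with 21 lists held 1 high fat mouse among its 5, so diet still differed between its groups. Such groupings do not show what chance alone gives, so chance is neither excluded nor shown for the number of lists.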

How the results depend on the processing

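In this part, the fits without high fat mice 1 and 2 and without high fat mouse 1 and low fat mouse 2 were chosen after the result was seen. The count of genes changed by diet stayed within 1.5 times of 4768 in the other fits at the 0.05 threshold, from 3210 without high fat mice 1 and 2 to 5317 over all rows of the table, and was 6105 at an adjusted p of 0.1. Leaving out 1 mouse gave 3759 to 4364 genes and 16 to 19 lists. A log2 difference of at least 1 left 377 genes changed by diet, 283 genes higher in high fat diet and 94 genes lower in high fat diet, by construction. Genes lower in high fat diet were 3056 with arrays centred on their medians, and genes higher in high fat diet were 1716 without high fat mice 1 and 2, where fewer samples entered. Mouse to mouse structure, the mean correlation between diets, was 0.952 with dim genes left out against 0.982, and the cause was not tested. Gene lists called were 0 with camera's estimated correlation, which lies above 0.01 for most lists. For cytokine and chemokine genes the estimate was 0.0132, yet their unadjusted camera p went from 0.000128 at the preset correlation to 0.00742. A higher correlation therefore need not account for all of the lost calls, and the cause was not tested.

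Without low fat mouse 2, gene Ucp1 turned to 0.20657 (adjusted p = 0.0081, range over settings 0.0081 to 0.815), and it was 0.21039 without high fat mouse 1 and low fat mouse 2; leaving out 1 mouse gave -0.48191 to 0.20657. Likewise list smooth muscle turned to 0.20919 and 0.16196, and leaving out 1 mouse gave -0.12592 to 0.20919. Both turns come from leaving out low fat mouse 2, and Ucp1 in the other mice lay below the medians of the arrays.

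Leaving out 1 mouse also called the lists endothelial cell, mesothelial cell, cholesterol synthesis, fatty acid oxidation and adipose expansion in at least 1 fit. It ended the call of list adipocyte progenitor and fibroblast without high fat mouse 4, high fat mouse 5, low fat mouse 2 and low fat mouse 4. It ended the calls of Scd1 (high fat mice 1, 2 and 3, low fat mice 1 and 4), H2-Eb1, Kdr, Ncr1, Pf4, Trp63 and Azgp1 in at least 1 fit, and Bank1, Ms4a1, Mx1 and Acta2 passed in at least 1; Synpo2 no longer passed without high fat mice 1 and 2. The cause was not tested. Mouse numbers do not pair the mice: deviations of same-numbered mice correlated at 0.08, 0.13, 0.07 and 0.05 across genes, and only number 2 matched its own best. With the mouse number as a replicate block, genes changed by diet were 4036 and gene lists called 17, with cholesterol synthesis gained and adipocyte progenitor and fibroblast lost, and Azgp1, H2-Eb1, Kdr, Ncr1, Scd1 and Trp63 no longer passed. Without detection calls, how far dim genes lie above background is unknown.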

Other observations

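The gene families here were chosen after the leading genes had been seen, so no family test is given and the counts describe these mice only. Genes singled out were also chosen after their values were seen. Of 25 vacuolar proton pump subunits 10 rose and 2 fell in high fat diet by limma over all genes (median 0.12), with Atp6v0a1 at 1.99-fold, Atp6v1b2 at 1.82-fold and Atp6v1a at 1.57-fold. Of 18 cathepsin genes, which encode lysosomal proteases, 8 rose and 1 fell, Ctso (-0.54), with a median of 0.07, and Ctsk was 5.93-fold higher and Ctss 3.77-fold. Of 12 Toll-like receptor genes 7 rose, among them Tlr13 (5.14-fold), Tlr8 (3.34-fold) and Tlr7 (2.17-fold).

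Of 21 glutathione S-transferase genes, which encode detoxifying enzymes, 13 fell and 1 rose, Gsto1 (0.51). Gsta3 was 2.82-fold lower, Gsta4 2.60-fold and Gstt1 1.91-fold. Of 10 acyl-CoA dehydrogenase genes 7 fell, such as Acadsb (1.66-fold lower), of 36 Hox genes 12, with Hoxa6 1.42-fold and Hoxc8 2.45-fold lower, and of 10 guanylate-binding protein genes 6, with Gbp11 3.64-fold lower. Gst and Gbp genes are families of similar copies whose probes can share signal.

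Of 1105 olfactory receptor genes 48 fell and 6 rose, with a median of -0.05. Over all 22180 genes 2026 fell and 2742 rose, so olfactory receptor genes passed less often than genes in general, in both directions. With arrays centred on their medians 117 fell, and with quantile normalization repeated 39 fell. Olfr111 and Olfr110, which lie on 1 chromosome, rose 6.96-fold and 2.82-fold in the values as deposited, from low fat means of 5.29 and 5.13 whose place above background was not determined.

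Single genes that stood out were Oxtr, the oxytocin receptor gene (5.21-fold higher), Mrc2, a collagen-binding receptor gene (5.02-fold higher), and Trdn, a calcium release gene of muscle (4.39-fold higher). Trdn lay at 7.48 to 8.13 in the high fat mice, highest in high fat mouse 5 and at 7.88 in high fat mouse 1. Its low fat mean was 5.73, whose place above background was not determined. Of the 12 listed skeletal muscle genes 0 passed by limma, with 0 at an unadjusted p under 0.05, and of 12 further ones Casq1 (1.15) and Cox6a2 (0.66) rose, both highest in high fat mouse 1.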
